A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

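RNA from 8 yeast cultures, 2 for each of 4 strains, was labelled from 10 µg of total RNA and hybridised to Affymetrix Yeast Genome 2.0 arrays, per the labels. The deposited values are probe set intensity on a linear scale, made with MAS5 per the submitters' processing notes, 1 column per array; the version and settings are not given in the sources used here. The values themselves show that each array had been scaled to a common mean, since the mean after trimming 2% at each end lay between 500.15 and 500.26. Replicates were not pooled. Of 10928 probe sets, 5498 were paired with 1 S. cerevisiae gene, 1 with several, 1746 belonged to another yeast species, 166 were controls and 3517 had no name in the table used. 12 symbols were updated through the gene table of assembly R64, which served for names and neighbouring genes and for no coordinates. 128 tested probe sets are shared between near-identical genes.

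Values were analysed as log2 of the deposited signal. The background level of an array was the 90th percentile of its probe sets for the other species, and probe sets above that level on at least 2 arrays were tested, 5496 in all for 5448 genes. A linear model of group means over all 8 arrays was fitted with limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend (4 residual degrees of freedom, median prior 6.56), and jsonlite 2.0.0 read the labels. Each of 6 contrasts was adjusted by Benjamini-Hochberg, and an adjusted p below 0.05 counted as a change. Where a gene was not above background on either array of a group, its fold was given as a bound, the geometric mean of the other group over the background level. 34 gene lists were tested with camera at a preset correlation of 0.01, using 1 probe set per gene, and again with an estimated correlation and with fry. The comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined.

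By that rule, POP2 and STM1 are named in every array. In each contrast, up to 10 genes with the largest rise and up to 10 with the largest fall may be named, among called genes whose groups do not overlap, and up to 4 called members of each list, by smallest p. Of these, the text gives mainly genes whose call held with any 1 array left out and under every scaling. The return towards BY4741 is the slope of the transformed strain's change on the A880 change, over genes chosen in 1 replicate number and measured in the other, as a share of the slope of a full return. Changes of unchanged groups sharing the A880 arrays were simulated 100 times.

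Alternatives were quantile normalization, equal array medians, a pseudocount, a floor at background, other filters on dim probe sets, all probe sets of the array, no intensity trend, the replicate number as a block, only the 4 arrays compared, stricter thresholds and each array left out in turn. Weights per group, 4 further lists and a return share without undetected genes were added after seeing the data. The code was tested on simulated data, with 200 of 5496 probe sets changed by 2-fold or 4-fold. Of the changes of 2-fold, it recovered 45.0% for A880 against BY4741, 41.0% for A880STM1 against A880, 42.0% for A880STM1K against A880, 32.0% for A880STM1K against A880STM1, 41.0% for A880STM1 against BY4741 and 34.0% for A880STM1K against BY4741. Of 4-fold changes it recovered 96.0%, 95.0%, 99.0%, 99.0%, 96.0% and 97.0% in the same order, and false calls were 5.37%, 9.93%, 7.24%, 3.68%, 4.20% and 3.68%. For A880 against BY4741 all 20 simulated lists of 30 genes shifted by log2 0.5 were found. Their genes were drawn independently, so lists of correlated genes are not covered. These simulations gave every group the same spread. In the data the median absolute log2 difference between replicates was 0.144 in BY4741, 0.118 in A880, 0.465 in A880STM1 and 0.388 in A880STM1K. The simulated rates therefore check the code and are not the error rates of these contrasts. Probe sets without a name, of the other species or with several genes were left out of the main test. Precision is limited by the number of arrays, 2 per group, and the outlying array of a pair cannot be told. Raw scans were not analysed here.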

Results

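RNA abundance was measured in 4 budding yeast strains on 8 expression arrays, 2 per strain from separate experiments and cultures. Arrays labelled BY4741, the name of a common laboratory strain, served as wild type. A880 is labelled as BY4741 without POP2, which encodes a nuclease subunit of CCR4-NOT, the complex that shortens messenger RNA tails. A880STM1 and A880STM1K are labelled as A880 that received STM1, the gene of a ribosome-associated protein, either unaltered or as R237K, with the position counted as in the labels. Cells grew on 2% glucose to an optical density of 1 and then for 12 hours on 2% glycerol, which yeast must respire. Between 99.5% and 99.9% of the 5498 probe sets assigned to 1 yeast gene lay above the background level of each array, which ranged from 5.15 to 8.40 signal units. Changes are log2 ± SE of the limma fit and signals are mean ± SD, with n = 2 arrays per group throughout. Unless a value says otherwise, every named gene with a change kept its call under both other scalings and with any 1 array left out.

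The genes named in the strain labels were read first. POP2 (YNR052C) gave a signal of 849 ± 48.8 on the BY4741 arrays and 0.336 ± 0.163, below background, on those labelled A880. On the arrays labelled A880STM1 and A880STM1K, which should also lack POP2, it was detected at 233 ± 74.4 and 215 ± 55.8, or 27.5% and 25.4% of BY4741. POP2 therefore goes against the labels of those 4 arrays. Probe positions were not available, but the same probe set lay below background on both A880 arrays. That argues against its position as the source of the signal, if these strains were made from A880 as labelled. STM1 (YLR150W) had 2304 ± 369.6 on BY4741, 3028 ± 96.2 on A880, 7234 ± 3121 on A880STM1 and 8420.3 ± 391.6 on A880STM1K arrays. STM1 was higher than on the A880 arrays by log2 1.19 ± 0.28, adjusted p = 0.0203, for A880STM1 and by 1.47 ± 0.28, adjusted p = 0.00207, for A880STM1K. The first call was lost without A880 replicate 1 (log2 1.15, adjusted p = 0.131), A880 replicate 2 (log2 1.22, adjusted p = 0.119) or A880STM1 replicate 1 (log2 0.73, adjusted p = 0.0734). STM1 signals on the A880STM1 arrays were 9441 in replicate 1 and 5027 in replicate 2, so its size there rests largely on replicate 1. URA3, a uracil synthesis gene often used as a selection marker, had 2.23 ± 1.54 on BY4741 arrays, at background, against 5299 ± 335 on A880, 4636 ± 453 on A880STM1 and 1617 ± 329.9 on A880STM1K. LEU2, a leucine synthesis gene missing from the usual BY4741, had 536 ± 8.43, 231 ± 24.6, 5558 ± 3035 and 8413 ± 1093 in the same order. Signal of LEU2, and of MET17 at 1447 ± 1037, on the BY4741 arrays leaves it open whether that label means the usual strain.

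**Figure D1:**
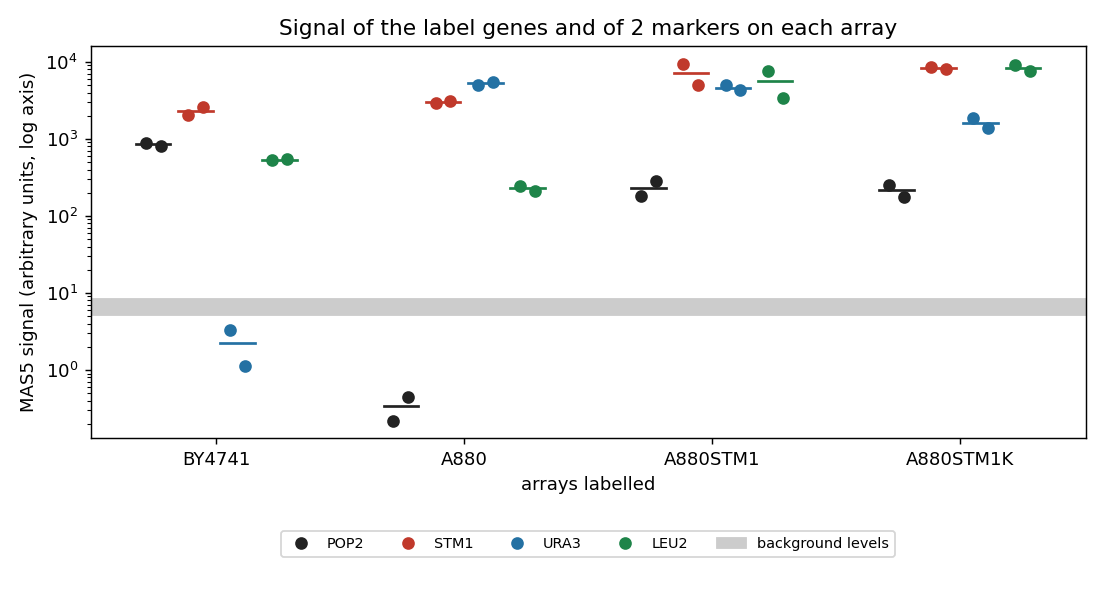
Signal of POP2, STM1, URA3 and LEU2 (MAS5 signal units, log axis) on each of the 8 arrays by strain label, with bars at the group means and a grey band over the background levels of the arrays. POP2 lies below the band only on the A880 arrays, at a mean of 0.336, and URA3 has a mean of 2.23 on the BY4741 arrays.

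POP2 was not alone in this pattern. 12 genes lay above 5 times background on BY4741 arrays and were not above background on either A880 array. Of these, 11 were again above background on both A880STM1 and on both A880STM1K arrays, and the exception was YBR013C. Among them were ARN2, a siderophore transporter, on chromosome VIII, and 4 genes on chromosome III, YCR099C, YCR101C, YCR102C and ADH7 (YCR105W). Others were PRM8 (YGL053W) and MST27 (YGL051W) on chromosome VII, and HXT9 (YJL219W), REE1 (YJL217W) and IMA5 (YJL216C) on chromosome X. By these systematic names, the genes within chromosomes III, VII and X lie near each other. The strains labelled A880 and BY4741 may therefore differ by more than POP2. In the other direction CAN1, the arginine permease, and URA3 were not above background on BY4741 arrays and were detected on all others. The A880STM1K arrays alone lacked ASP3-1, a cell-wall asparaginase, and YLR156W, whose probe sets are shared with near-identical copies and so are uncertain.

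**Figure D2:**
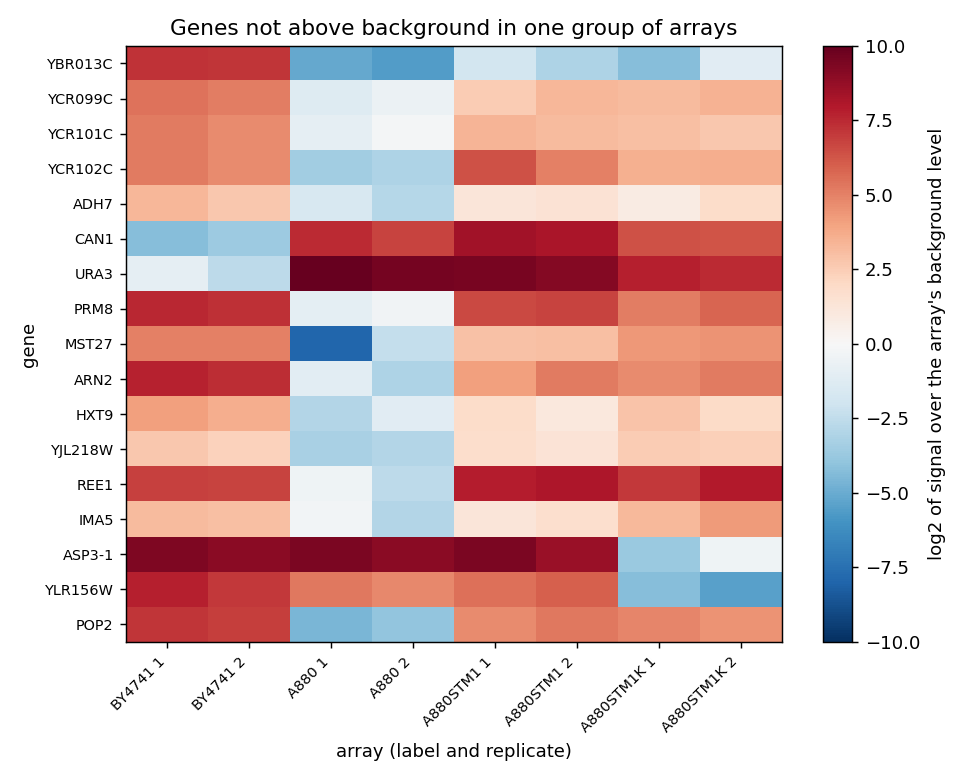
Heat map of 17 genes (vertical) on 8 arrays (horizontal) in log2 signal over the background level of the array, for genes not above background in 1 strain and over 5 times background in another. Of the 12 genes missing from the A880 arrays and over 5 times background on BY4741 arrays, 11 are present on all 4 arrays of the transformed strains.

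The comparison of A880 with BY4741 was meant to ask which transcripts differ when POP2 is missing during growth on glycerol. Other genes besides POP2 were detected on the arrays of only 1 of these labels, so a change cannot be assigned to POP2 alone. On the A880 arrays POP2 was at least 140.4-fold lower (adjusted p = 1.56e-07), and CCR4, the other nuclease of the same complex, rose by log2 1.69 ± 0.21 (adjusted p = 0.000942). Also rising were CTR3, a copper transporter, by log2 4.39 ± 0.36, STL1, the glycerol importer, by 3.70 ± 0.37, IME1, the inducer of meiosis, by 3.51 ± 0.27 and PIR1, a cell wall protein, by 2.92 ± 0.26 (largest adjusted p = 0.000302). Genes that fell were RDS1 at log2 -5.84 ± 0.82, COS8 at -5.76 ± 0.29, GSY2, glycogen synthase, at -2.04 ± 0.26 and CRC1, the mitochondrial carnitine carrier, at -2.05 ± 0.25 (largest adjusted p = 0.00205). MPT5, an RNA-binding protein that recruits CCR4-NOT, rose by log2 1.83 ± 0.29 (adjusted p = 0.00421), and FUN12, a translation initiation factor, rose by log2 1.67 ± 0.22 (adjusted p = 0.00142). URA3 and CAN1, not above background on BY4741 arrays, were higher: URA3 at least 817-fold and CAN1 at least 130.3-fold (largest adjusted p = 1.04e-07). The limma test called 764 of 5496 probe sets, 424 higher and 340 lower, with a 2-fold change or more for 585. The split with equal array medians was 413 higher and 554 lower, while the median change of all tested probe sets went from log2 0.017 to -0.10. The count was 95 without BY4741 replicate 1, 150 without BY4741 replicate 2, 164 without A880 replicate 1 and 127 without A880 replicate 2. Other settings gave 1383 with quantile normalization, 2992 with only the 4 arrays compared and 3140.0 with array weights per group, a setting chosen after seeing the data.

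Ergosterol, mitochondrial ribosome, chaperone and proteasome genes were higher on the A880 arrays. Ergosterol synthesis genes, the membrane sterol pathway, had 9 of 23 members rise and 0 fall (11 and 0 adjusted over the list alone), among them ERG5 by log2 2.94 ± 0.33, ERG3 by 2.44 ± 0.35 and ERG25 by 2.17 ± 0.24 (largest adjusted p = 0.00218). Camera gave the ergosterol list adjusted p = 0.000685, and adjusted p = 0.874 with an estimated correlation, at a median of log2 0.67, or 0.66 relative to all tested genes. For mitochondrial ribosomal proteins 10 of 66 members rose and 0 fell (21 and 0 adjusted over the list alone), among them MRPL32 by log2 2.17 ± 0.22 (adjusted p = 0.000336). Mitochondrial ribosomal protein members had a median of log2 0.53, or 0.52 relative to all tested genes (camera adjusted p = 5.79e-06, and adjusted p = 0.874 with an estimated correlation). Of 23 chaperones, the protein folding factors, 6 rose and 0 fell (10 and 0 adjusted over the list alone), among them SSA2 by log2 2.30 ± 0.35 (adjusted p = 0.00329). The chaperone median was log2 0.57, or 0.55 relative to all tested genes (camera adjusted p = 0.00105, and adjusted p = 0.874 with an estimated correlation). Among 33 proteasome genes, which build the main protein degradation machine, 10 rose and 0 fell (18 and 0 adjusted over the list alone). Camera gave the proteasome list adjusted p = 4.46e-06, and adjusted p = 0.874 with an estimated correlation, at a median of log2 0.62, or 0.60 relative to all tested genes. Iron regulon genes, which act in iron uptake under AFT1 control, had 0 of 17 members rise and 8 fall (0 and 10 adjusted over the list alone), among them ARN2, lower by at least 201-fold (adjusted p = 2.48e-06). Iron regulon members had a median of log2 -0.79, or -0.81 relative to all tested genes (camera adjusted p = 0.000110, and adjusted p = 0.874 with an estimated correlation). Since ARN2 lies at a bound far below that median, the median does not depend on it. The camera test uses the values of every member and was not run without ARN2. For gluconeogenesis and glyoxylate cycle genes 0 of 18 members rose and 5 fell (0 and 6 adjusted over the list alone), among them CRC1 at log2 -2.05 ± 0.25 (adjusted p = 0.000882). The gluconeogenesis median was log2 -0.50, or -0.52 relative to all tested genes (camera adjusted p = 0.00105, and adjusted p = 0.541 with an estimated correlation). The list test was not passed by CCR4-NOT subunits, of which 2 of 9 rose and 1 fell (2 and 1 adjusted over the list alone), at a median of log2 -0.077 and camera adjusted p = 0.971 (0.991 with an estimated correlation), or by messenger RNA decay factors, of which 2 of 21 rose and 2 fell (2 and 3 adjusted over the list alone), at a median of log2 -0.12 and camera adjusted p = 0.971 (0.991 with an estimated correlation). The other 2 lists that passed camera lost the call under another scaling or without 1 array, at the adjusted p given. With quantile normalization, it was lost for trehalose and glycogen (0.0594). With equal array medians, it was lost for trehalose and glycogen (0.0552). Without BY4741 replicate 2, it was lost for trehalose and glycogen (0.0548) and meiosis (0.0548). Without A880 replicate 1, it was lost for trehalose and glycogen (0.128). Without A880 replicate 2, it was lost for meiosis (0.147).

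The comparison of A880STM1 with A880 asks what added STM1 changes when POP2 is absent, with the limit that POP2 was detected on the arrays labelled A880STM1. Mating genes were among the strongest falls: STE18, the G protein gamma subunit of the pheromone pathway, at log2 -5.60 ± 0.30, FUS3, its MAP kinase, at -4.87 ± 0.34, AGA2, an a-agglutinin subunit, at -3.33 ± 0.29 and FAR1, which arrests the cell cycle for mating, at -3.14 ± 0.36 (largest adjusted p = 0.000512). Falling too were RME1, a repressor of meiosis expressed in haploid cells, at log2 -3.07 ± 0.24 and BAR1, the alpha-factor protease, at -2.99 ± 0.39 (largest adjusted p = 0.00116). Genes not detected on the A880 arrays came back with POP2, such as REE1 at least 296-fold, ARN2 at least 29.5-fold and PRM8 at least 119-fold (largest adjusted p = 4.39e-05) higher. Among other genes that rose were LEU2 by log2 4.48 ± 0.33, COX5B, the cytochrome oxidase subunit of low oxygen, by 3.98 ± 0.36, TSA2, a peroxiredoxin, by 3.58 ± 0.41 and HXK2, the main hexokinase of glucose growth, by 2.997 ± 0.36 (largest adjusted p = 0.000676). The limma test called 1094 of 5496 probe sets, 375 higher and 719 lower, with a 2-fold change or more for 771. The split with equal array medians was 630 higher and 321 lower, and with quantile normalization 547 and 521, while the median change of all tested probe sets went from log2 -0.27 to 0.12. The count was 179 without A880 replicate 1, 124 without A880 replicate 2, 277 without A880STM1 replicate 1 and 2283 without A880STM1 replicate 2.

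Mating genes were lower on the arrays labelled A880STM1. Of 7 a-cell-specific genes, which serve mating of the a type, 0 rose and 5 fell (0 and 7 adjusted over the list alone), among them MFA2 at log2 -2.24 ± 0.31 and BAR1 at -2.99 ± 0.39 (largest adjusted p = 0.00160). Camera gave the a-cell-specific list adjusted p = 4.27e-05, and adjusted p = 0.316 with an estimated correlation, at a median of log2 -2.24, or -1.96 relative to all tested genes. Among 15 pheromone response genes, genes induced or used in mating, 0 rose and 7 fell (0 and 7 adjusted over the list alone), among them GPA1 at log2 -2.44 ± 0.30 and PRM2 at -2.48 ± 0.37 (largest adjusted p = 0.00270). Pheromone response members had a median of log2 -1.25, or -0.97 relative to all tested genes (camera adjusted p = 0.000136, and adjusted p = 0.4995 with an estimated correlation). Mitochondrial ribosomal proteins had 0 of 66 members rise and 16 fall (1 and 21 adjusted over the list alone). The mitochondrial ribosomal protein median was log2 -0.50, or -0.23 relative to all tested genes (camera adjusted p = 0.00236, and adjusted p = 0.865 with an estimated correlation), with -0.70 in replicate 1 and -0.39 in replicate 2, and -0.11 with equal array medians. For cytosolic ribosomal proteins, the structural proteins of cytosolic ribosomes, 19 of 127 members rose and 0 fell (19 and 0 adjusted over the list alone), among them RPP2A by log2 1.80 ± 0.32 (adjusted p = 0.00657). Camera gave the cytosolic ribosomal protein list adjusted p = 3.43e-17, and adjusted p = 0.535 with an estimated correlation, at a median of log2 0.60, or 0.87 relative to all tested genes, with 1.09 in replicate 1 and 0.12 in replicate 2, and 0.38 with quantile normalization, and 0.99 with equal array medians. Of their probe sets, 26 are shared with near-identical copies. Of 35 respiratory chain and ATP synthase genes, 4 rose and 0 fell (11 and 0 adjusted over the list alone), among them CYC1 by log2 2.21 ± 0.28 (adjusted p = 0.000842). Respiratory chain members had a median of log2 0.57, or 0.84 relative to all tested genes (camera adjusted p = 8.93e-10, and adjusted p = 0.4995 with an estimated correlation), with 0.76 in replicate 1 and 0.29 in replicate 2, and 0.21 with quantile normalization, and 0.96 with equal array medians. Among 20 oxidative stress defence genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), among them OYE2 by log2 2.53 ± 0.26 and TRR1 by 2.68 ± 0.34 (largest adjusted p = 0.000890). The oxidative stress median was log2 0.37, or 0.64 relative to all tested genes (camera adjusted p = 0.000109, and adjusted p = 0.4995 with an estimated correlation), with 0.75 in replicate 1 and 0.10 in replicate 2, and 0.18 with quantile normalization, and 0.76 with equal array medians. Amino acid biosynthesis genes had 11 of 38 members rise and 2 fall (16 and 2 adjusted over the list alone). Camera gave the amino acid list adjusted p = 7.78e-07, and adjusted p = 0.535 with an estimated correlation, at a median of log2 0.57, or 0.84 relative to all tested genes, with 1.00 in replicate 1 and 0.28 in replicate 2, and 0.95 with equal array medians. Of genes in other lists, PHO84, the phosphate importer, by log2 2.83 ± 0.34, HMX1, heme oxygenase, by 2.47 ± 0.25 and GSY1 by 2.26 ± 0.29 (largest adjusted p = 0.00100) rose.

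The other 12 lists that passed camera lost the call under another scaling or without 1 array, at the adjusted p given. It was lost with quantile normalization for TCA cycle (0.8999), gluconeogenesis (0.824), glycolysis (0.490), hexose transporters (0.219), general stress response (0.998, in the other direction), trehalose and glycogen (0.103), phosphate regulon (0.0801), histones (0.824), anaerobic genes (0.0535), COS genes (0.0717) and auxotrophic markers (0.0933). It was lost with equal array medians for hexose transporters (0.0677), anaerobic genes (0.0576) and auxotrophic markers (0.0884). It was lost without A880 replicate 1 for TCA cycle (0.0739) and anaerobic genes (0.0673). It was lost without A880STM1 replicate 1 for glycolysis (0.128), hexose transporters (0.128), general stress response (0.113), histones (0.166) and auxotrophic markers (0.0667). It was lost without A880STM1 replicate 2 for phosphate regulon (0.0987), iron regulon (0.147) and anaerobic genes (0.0869).

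The comparison of A880STM1K with A880 puts the same question for STM1 R237K, with POP2 again detected on the arrays labelled A880STM1K. Genes for using carbon sources other than glucose fell strongly: FBP1, the gluconeogenic bisphosphatase, at log2 -5.56 ± 0.34, SFC1, a mitochondrial succinate carrier, at -5.51 ± 0.31, CAT8, the activator of gluconeogenic genes, at -3.10 ± 0.31 and MLS1, malate synthase, at -2.32 ± 0.23 (largest adjusted p = 6.48e-05). Fatty acid oxidation genes POT1 at log2 -4.66 ± 0.37 and POX1 at -4.14 ± 0.29 (largest adjusted p = 1.75e-05) fell as well, as did the glycerol importer STL1 at log2 -4.57 ± 0.37 (adjusted p = 1.80e-05). Genes that rose included SAM2, S-adenosylmethionine synthetase, by log2 3.97 ± 0.56, SER3, the entry enzyme of serine synthesis, by 3.70 ± 0.31, MVD1, of the mevalonate pathway, by 2.96 ± 0.24 and TEF4, an elongation factor subunit, by 2.73 ± 0.45 (largest adjusted p = 0.000960). Further rises were CYC1, cytochrome c, by log2 3.91 ± 0.28 and HXK2 by 3.67 ± 0.36 (largest adjusted p = 5.73e-05). The limma test called 2589 of 5496 probe sets, 1051 higher and 1538 lower, with a 2-fold change or more for 1900. The split with equal array medians was 1610 higher and 1099 lower, while the median change of all tested probe sets went from log2 -0.17 to 0.18. The count was 1532 without A880 replicate 1 and 1577 without A880 replicate 2.

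Gluconeogenesis and peroxisome genes were lower and ribosomal proteins higher on the arrays labelled A880STM1K. For gluconeogenesis and glyoxylate cycle genes 0 of 18 members rose and 18 fell (0 and 18 adjusted over the list alone). Gluconeogenesis members had a median of log2 -2.30, or -2.14 relative to all tested genes (camera adjusted p = 9.60e-08, and adjusted p = 0.126 with an estimated correlation). Of 16 peroxisome and fatty acid oxidation genes, 0 rose and 15 fell (0 and 15 adjusted over the list alone), among them CTA1 at log2 -3.33 ± 0.28 and IDP3 at -2.31 ± 0.24 (largest adjusted p = 6.67e-05). The peroxisome median was log2 -2.42, or -2.26 relative to all tested genes (camera adjusted p = 7.91e-07, and adjusted p = 0.638 with an estimated correlation). Among 127 cytosolic ribosomal proteins, 101 rose and 0 fell (107 and 1 adjusted over the list alone), among them RPL17B by log2 2.003 ± 0.28, RPS7A by 1.78 ± 0.25 and RPL15A by 2.17 ± 0.33 (largest adjusted p = 0.000619). Camera gave the cytosolic ribosomal protein list adjusted p = 8.67e-18, and adjusted p = 0.638 with an estimated correlation, at a median of log2 1.05, or 1.22 relative to all tested genes, with 1.38 in replicate 1 and 0.74 in replicate 2. Mitochondrial ribosomal proteins had 34 of 66 members rise and 1 fall (34 and 1 adjusted over the list alone), among them MRPL4 by log2 1.86 ± 0.25, MRPS35 by 1.86 ± 0.26 and MRP4 by 2.01 ± 0.29 (largest adjusted p = 0.000423). Mitochondrial ribosomal protein members had a median of log2 0.68, or 0.85 relative to all tested genes (camera adjusted p = 2.01e-08, and adjusted p = 0.638 with an estimated correlation), with 0.40 in replicate 1 and 1.02 in replicate 2, and 1.03 with equal array medians. For translation factors 12 of 29 members rose and 0 fell (12 and 0 adjusted over the list alone), among them RPG1 by log2 1.98 ± 0.23 and YEF3 by 2.27 ± 0.39 (largest adjusted p = 0.00119). The translation factor median was log2 0.53, or 0.70 relative to all tested genes (camera adjusted p = 0.000422, and adjusted p = 0.638 with an estimated correlation), with 0.71 in replicate 1 and 0.33 in replicate 2, and 0.88 with equal array medians.

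Amino acid and sterol genes rose in the same comparison. Of 38 amino acid biosynthesis genes, 30 rose and 0 fell (35 and 0 adjusted over the list alone), among them ILV3 by log2 2.09 ± 0.24, ARG4 by 2.27 ± 0.27 and BAT1 by 2.96 ± 0.36 (largest adjusted p = 0.000189). Camera gave the amino acid list adjusted p = 3.03e-12, and adjusted p = 0.638 with an estimated correlation, at a median of log2 1.54, or 1.70 relative to all tested genes, with 1.84 in replicate 1 and 1.23 in replicate 2. Among 21 sulfur amino acid genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone), among them MET13 by log2 2.72 ± 0.22 and SAM1 by 3.60 ± 0.60 (largest adjusted p = 0.000977). Sulfur members had a median of log2 2.45, or 2.62 relative to all tested genes (camera adjusted p = 4.40e-06, and adjusted p = 0.638 with an estimated correlation), with 1.03 in replicate 1 and 3.27 in replicate 2. Ergosterol synthesis genes had 18 of 23 members rise and 0 fall (19 and 0 adjusted over the list alone), among them ERG4 by log2 2.32 ± 0.26 and ERG26 by 2.63 ± 0.33 (largest adjusted p = 0.000200). The ergosterol median was log2 1.20, or 1.36 relative to all tested genes (camera adjusted p = 5.13e-08, and adjusted p = 0.638 with an estimated correlation). For a-cell-specific genes 0 of 7 members rose and 5 fell (0 and 5 adjusted over the list alone), among them MFA1 at log2 -3.30 ± 0.37 and AGA2 at -2.59 ± 0.29 (largest adjusted p = 0.000120). Camera gave the a-cell-specific list adjusted p = 0.00484, and adjusted p = 0.530 with an estimated correlation, at a median of log2 -1.51, or -1.34 relative to all tested genes. Mating genes that fell were STE18 at log2 -5.05 ± 0.30 and FUS3 at -4.16 ± 0.34 (largest adjusted p = 1.80e-05). The other 6 lists that passed camera lost the call under another scaling or without 1 array, at the adjusted p given. With quantile normalization, it was lost for glycolysis (0.0804), hexose transporters (0.202), trehalose and glycogen (0.146) and cell wall (0.118). With equal array medians, it was lost for hexose transporters (0.193). Without A880 replicate 1, it was lost for trehalose and glycogen (0.0783) and anaerobic genes (0.0725). Without A880STM1K replicate 1, it was lost for hexose transporters (0.123), cell wall (0.0600), proteasome (0.0596) and anaerobic genes (0.0596). Without A880STM1K replicate 2, it was lost for trehalose and glycogen (0.173).

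The comparison of A880STM1K with A880STM1 asks whether cells with the R237K form differ from those with unaltered STM1. POP2 was detected on the arrays of both labels and no difference in its signal was detected (log2 -0.10 ± 0.45, adjusted p = 0.876), nor in that of STM1 (log2 0.29 ± 0.28, adjusted p = 0.454), except without A880STM1 replicate 1, where STM1 passed at log2 0.74, adjusted p = 0.0239. The ratio of 3-prime to 5-prime signal, a geometric mean over 7 control genes, was 1.84 and 1.83 on the A880STM1K arrays and 1.53 and 1.51 on the A880STM1 arrays. Lower on the arrays labelled A880STM1K were SFC1 at log2 -5.57 ± 0.31, FBP1 at -4.84 ± 0.34, SRX1, sulfiredoxin, at -4.68 ± 0.38 and POT1, the peroxisomal thiolase, at -4.33 ± 0.37 (largest adjusted p = 4.45e-05). Higher there were RSB1, a lipid transporter, by log2 4.28 ± 0.33, MIG2, a glucose repressor, by 3.91 ± 0.39, CLN3, a G1 cyclin, by 3.52 ± 0.36 and PDR5, a drug efflux pump, by 3.23 ± 0.25 (largest adjusted p = 9.28e-05). Also higher were MSF1, a mitochondrial tRNA synthetase, by log2 3.74 ± 0.31, MTO1, a tRNA modification enzyme, by 3.60 ± 0.36 and RSM25 by 3.04 ± 0.31 (largest adjusted p = 9.92e-05). The limma test called 1925 of 5496 probe sets, 984 higher and 941 lower, with a 2-fold change or more for 1364. Other settings gave 1179 with only the 4 arrays compared and 794 with array weights per group, a setting chosen after seeing the data.

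Gluconeogenesis, peroxisome and respiratory chain genes were lower and mitochondrial ribosomal proteins higher on the arrays labelled A880STM1K. Of 18 gluconeogenesis and glyoxylate cycle genes, 0 rose and 17 fell (0 and 17 adjusted over the list alone), among them YAT1 at log2 -2.92 ± 0.25 and SIP4 at -3.21 ± 0.30 (largest adjusted p = 6.84e-05). Gluconeogenesis members had a median of log2 -2.59 (camera adjusted p = 8.52e-13, and still passed at adjusted p = 0.0435 with an estimated correlation). Among 16 peroxisome and fatty acid oxidation genes, 0 rose and 13 fell (0 and 14 adjusted over the list alone), among them POX1 at log2 -3.42 ± 0.29 and ECI1 at -2.73 ± 0.26 (largest adjusted p = 6.92e-05). The peroxisome median was log2 -2.33 (camera adjusted p = 5.49e-09, and adjusted p = 0.694 with an estimated correlation). Respiratory chain and ATP synthase genes had 2 of 35 members rise and 19 fall (2 and 21 adjusted over the list alone), among them QCR6 at log2 -2.56 ± 0.25, ATP14 at -1.94 ± 0.20 and ATP17 at -2.33 ± 0.25 (largest adjusted p = 0.000138). Camera gave the respiratory chain list adjusted p = 2.24e-06, and adjusted p = 0.694 with an estimated correlation, at a median of log2 -0.69, with -1.20 in replicate 1 and -0.37 in replicate 2. For mitochondrial ribosomal proteins 50 of 66 members rose and 0 fell (55 and 0 adjusted over the list alone), among them MRPL15 by log2 2.55 ± 0.24, MRPL3 by 2.58 ± 0.25 and MRP4 by 2.93 ± 0.29 (largest adjusted p = 7.37e-05). Mitochondrial ribosomal protein members had a median of log2 1.23 (camera adjusted p = 7.21e-14, and adjusted p = 0.694 with an estimated correlation). Of 29 translation factors, 12 rose and 0 fell (16 and 0 adjusted over the list alone), among them RPG1 by log2 1.99 ± 0.23 and NIP1 by 1.87 ± 0.30 (largest adjusted p = 0.00113). The translation factor median was log2 0.73 (camera adjusted p = 0.000303, and adjusted p = 0.694 with an estimated correlation). Among 38 amino acid biosynthesis genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone), among them ILV3 by log2 2.36 ± 0.24, SER3 by 2.41 ± 0.31 and BAT1 by 2.59 ± 0.36 (largest adjusted p = 0.000518). Camera gave the amino acid list adjusted p = 1.11e-05, and adjusted p = 0.694 with an estimated correlation, at a median of log2 0.85. Ergosterol synthesis genes had 16 of 23 members rise and 0 fall (19 and 0 adjusted over the list alone), among them ERG4 by log2 2.35 ± 0.26 and ERG3 by 2.58 ± 0.35 (largest adjusted p = 0.000442). Ergosterol members had a median of log2 1.23 (camera adjusted p = 2.47e-07, and adjusted p = 0.694 with an estimated correlation).

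Lists of cytosolic ribosome production depended on single arrays in this comparison. For cytosolic ribosomal proteins 18 of 127 members rose and 2 fell (9 and 0 adjusted over the list alone), at a median of log2 0.44 and camera adjusted p = 0.000539, with adjusted p = 0.857 with an estimated correlation. Its median was log2 0.26 in replicate 1 and 0.60 in replicate 2. Ribosome biogenesis genes had the same dependence: 7 of 70 members rose and 0 fell (0 and 0 adjusted over the list alone), at a median of log2 0.49 and camera adjusted p = 0.0201, with adjusted p = 0.862 with an estimated correlation, with medians of 1.05 in replicate 1 and 0.062 in replicate 2. With these included, 11 lists that passed camera lost the call under another scaling or without 1 array, at the adjusted p given. With quantile normalization, it was lost for general stress response (0.0709), phosphate regulon (0.0610), cell wall (0.0610) and pheromone response (0.0641). With equal array medians, it was lost for general stress response (0.0780), phosphate regulon (0.0628) and cell wall (0.0640). Without A880STM1 replicate 1, it was lost for general stress response (0.533), chaperones (0.307), phosphate regulon (0.0681), pheromone response (0.0654) and proteasome (0.142). Without A880STM1 replicate 2, it was lost for cytosolic ribosomal proteins (0.528, in the other direction), ribosome biogenesis (0.725), phosphate regulon (0.0690), cell wall (0.343) and alpha-cell-specific genes (0.0736). Without A880STM1K replicate 1, it was lost for cytosolic ribosomal proteins (0.0617), ribosome biogenesis (0.110, in the other direction), general stress response (0.417), phosphate regulon (0.110), cell wall (0.161), pheromone response (0.0917), proteasome (0.361) and autophagy (0.180). Without A880STM1K replicate 2, it was lost for sulfur amino acids (0.0819).

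**Figure D3:**
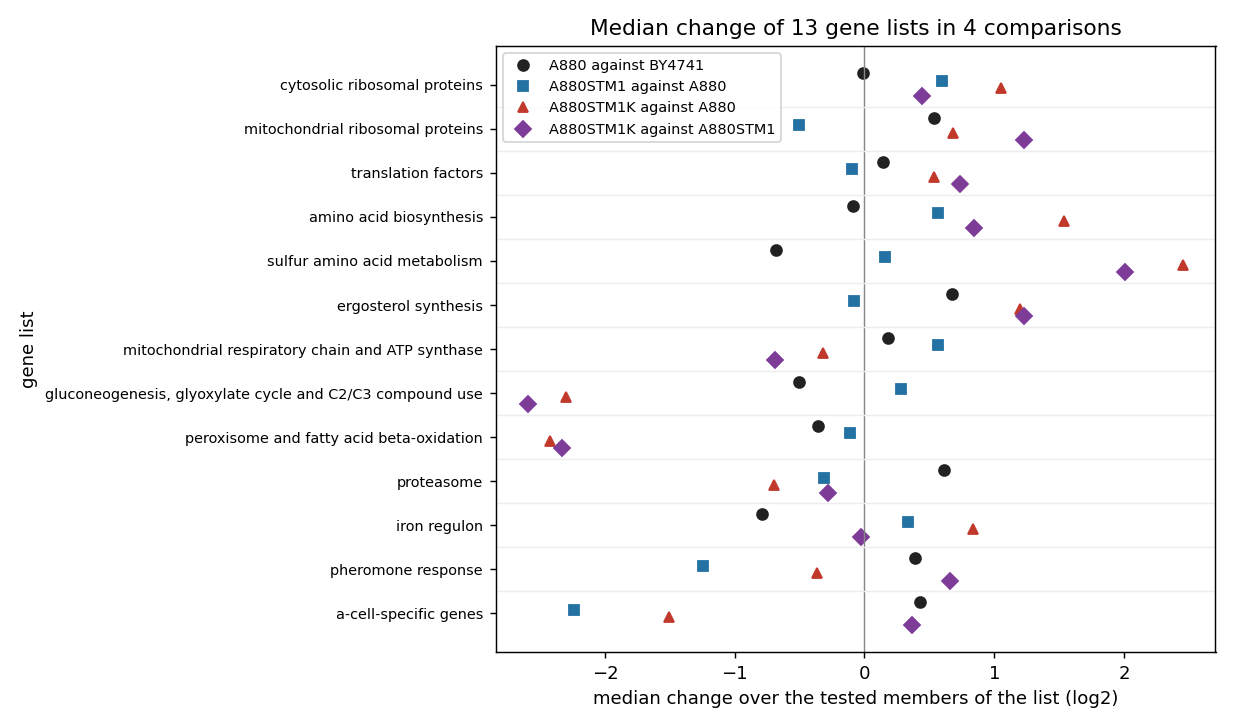
Median log2 change of 13 gene lists (vertical) in the comparisons of A880 with BY4741, of both transformed strains with A880 and of A880STM1K with A880STM1 (horizontal axis in log2). Gluconeogenesis lies at -2.30 in A880STM1K against A880, and the sign of a median turns under another scaling for cytosolic ribosomal proteins (quantile normalization) in A880 against BY4741; translation factors (equal array medians), ergosterol synthesis (quantile normalization and equal array medians), gluconeogenesis (quantile normalization), peroxisome (equal array medians) and proteasome (equal array medians) in A880STM1 against A880; respiratory chain (equal array medians) in A880STM1K against A880.

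Setting the transformed strains against BY4741 asks how far each lay from wild type; POP2 was detected on their arrays at lower signal than on BY4741, so the directions are those of the arrays labelled A880STM1 and A880STM1K. On the A880STM1 arrays CAN1 at least 338-fold and URA3 at least 714-fold (largest adjusted p = 1.24e-07) were higher, and CTR3 by log2 4.47 ± 0.36, SUC2, invertase, by 3.43 ± 0.39 and IME4, a methyltransferase of meiotic cells, by 3.44 ± 0.39 (largest adjusted p = 0.000701) rose. STE18 at log2 -5.61 ± 0.30, FUS3 at -4.48 ± 0.34 and MFA2, an a-factor gene, at -3.63 ± 0.31 (largest adjusted p = 0.000175) fell, as did YBR013C, lower at least 132-fold (adjusted p = 0.000267). POP2 itself was lower by log2 -1.90 ± 0.45, adjusted p = 0.0270, a call lost without BY4741 replicate 1 (adjusted p = 0.192), BY4741 replicate 2 (0.184) or A880STM1 replicate 1 (0.182). The limma test called 643 of 5496 probe sets, 297 higher and 346 lower, with a 2-fold change or more for 488. The split with equal array medians was 358 higher and 193 lower, while the median change of all tested probe sets went from log2 -0.24 to 0.035. The count was 103 without BY4741 replicate 1, 99 without BY4741 replicate 2, 97 without A880STM1 replicate 1 and 1951 without A880STM1 replicate 2. The same test gave 362 with array weights per group, a setting chosen after seeing the data.

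Respiratory chain and ergosterol genes were higher on the arrays labelled A880STM1 than on BY4741. For respiratory chain and ATP synthase genes 15 of 35 members rose and 0 fell (23 and 0 adjusted over the list alone), among them CYC1 by log2 2.70 ± 0.28, NDI1 by 2.17 ± 0.26 and NDE1 by 1.64 ± 0.21 (largest adjusted p = 0.00127). The respiratory chain median was log2 0.65, or 0.89 relative to all tested genes (camera adjusted p = 3.97e-15, and adjusted p = 0.498 with an estimated correlation), with 0.93 in replicate 1 and 0.45 in replicate 2, and 0.39 with quantile normalization. Of 23 ergosterol synthesis genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone), among them ERG6 by log2 2.40 ± 0.29 and ERG5 by 2.55 ± 0.33 (largest adjusted p = 0.00140). Camera gave the ergosterol list adjusted p = 4.50e-07, and adjusted p = 0.498 with an estimated correlation, at a median of log2 0.65, or 0.89 relative to all tested genes, with 0.43 in replicate 1 and 0.92 in replicate 2. Among 127 cytosolic ribosomal proteins, 11 rose and 0 fell (0 and 0 adjusted over the list alone). Cytosolic ribosomal protein members had a median of log2 0.64, or 0.87 relative to all tested genes (camera adjusted p = 2.12e-18, and adjusted p = 0.498 with an estimated correlation), with 1.08 in replicate 1 and 0.18 in replicate 2. Chaperones had 7 of 23 members rise and 0 fall (11 and 0 adjusted over the list alone), among them SSA4 by log2 1.96 ± 0.27 (adjusted p = 0.00203). The chaperone median was log2 0.57, or 0.80 relative to all tested genes (camera adjusted p = 9.09e-08, and adjusted p = 0.498 with an estimated correlation), with 1.02 in replicate 1 and 0.15 in replicate 2. For amino acid biosynthesis genes 8 of 38 members rose and 1 fell (12 and 1 adjusted over the list alone). Camera gave the amino acid list adjusted p = 2.26e-05, and adjusted p = 0.553 with an estimated correlation, at a median of log2 0.47, or 0.70 relative to all tested genes, with 0.77 in replicate 1 and 0.19 in replicate 2, and 0.74 with equal array medians. Of 21 cell wall genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone), among them PIR1 by log2 2.43 ± 0.26 and PIR3 by 1.90 ± 0.25 (largest adjusted p = 0.00140). Cell wall members had a median of log2 0.22, or 0.46 relative to all tested genes (camera adjusted p = 0.00488, and adjusted p = 0.498 with an estimated correlation), with 0.50 in replicate 1 and 0.26 in replicate 2, and 0.49 with equal array medians.

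Meiosis genes also passed the list test and mating genes were lower there. Among 16 meiosis and sporulation genes, 3 rose and 1 fell (5 and 2 adjusted over the list alone), among them IME1 by log2 2.85 ± 0.27 and RED1 by 2.02 ± 0.30 (largest adjusted p = 0.00313). The meiosis median was log2 0.59, or 0.82 relative to all tested genes (camera adjusted p = 0.00447, and adjusted p = 0.498 with an estimated correlation), with 0.16 in replicate 1 and 0.98 in replicate 2. The a-cell-specific genes had 0 of 7 members rise and 6 fall (0 and 6 adjusted over the list alone). Camera gave the a-cell-specific list adjusted p = 5.60e-05, and adjusted p = 0.360 with an estimated correlation, at a median of log2 -1.73, or -1.49 relative to all tested genes. For pheromone response genes 0 of 15 members rose and 4 fell (0 and 6 adjusted over the list alone). Pheromone response members had a median of log2 -0.66, or -0.42 relative to all tested genes (camera adjusted p = 0.00263, and adjusted p = 0.498 with an estimated correlation), with -0.39 with equal array medians. Of 33 proteasome genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone). The proteasome median was log2 0.32, or 0.55 relative to all tested genes (camera adjusted p = 2.12e-05, and adjusted p = 0.553 with an estimated correlation), with 0.51 in replicate 1 and 0.20 in replicate 2, and 0.17 with quantile normalization, and 0.59 with equal array medians. Among 4 auxotrophic markers, genes altered or deleted in the usual BY4741, 2 rose and 0 fell (2 and 0 adjusted over the list alone), among them LEU2 by log2 3.26 ± 0.33 (adjusted p = 0.000396). Camera gave the marker list adjusted p = 0.000101, and adjusted p = 0.360 with an estimated correlation, at a median of log2 1.85, or 2.08 relative to all tested genes, with 2.68 in replicate 1 and 1.48 in replicate 2. URA3, a member, lies at a bound above that median. The other 6 lists that passed camera lost the call under another scaling or without 1 array, at the adjusted p given. With quantile normalization, it was lost for TCA cycle (0.388), glycerol (0.0815), general stress response (0.219) and oxidative stress (0.101). With equal array medians, it was lost for peroxisome (0.0578). Without BY4741 replicate 1, it was lost for peroxisome (0.0823). Without A880STM1 replicate 1, it was lost for glycolysis (0.0631), general stress response (0.0578), oxidative stress (0.0578) and peroxisome (0.0796). Without A880STM1 replicate 2, it was lost for peroxisome (0.0699).

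On the arrays labelled A880STM1K large changes from BY4741 included falls in SFC1 at log2 -6.36 ± 0.31, FBP1 at -5.18 ± 0.34, POT1 at -4.84 ± 0.37 and ICL1, isocitrate lyase, at -4.38 ± 0.34 (largest adjusted p = 1.18e-05) and rises in CYC1 by log2 4.40 ± 0.28, ERG5 by 4.27 ± 0.33, YHB1, a flavohemoglobin, by 4.01 ± 0.34 and PIR3 by 3.99 ± 0.25 (largest adjusted p = 1.85e-05). MSF1 by log2 4.76 ± 0.31, MIG2 by 4.14 ± 0.39 and CLN3 by 3.51 ± 0.36 (largest adjusted p = 4.88e-05) rose as well. POP2 was lower by log2 -2.003 ± 0.45, adjusted p = 0.00422, and STM1 higher by 1.88 ± 0.28, adjusted p = 0.000439. The limma test called 2720 of 5496 probe sets, 1164 higher and 1556 lower, with a 2-fold change or more for 1989. The split with equal array medians was 1489 higher and 1306 lower, while the median change of all tested probe sets went from log2 -0.11 to 0.12. The count was 1755 without BY4741 replicate 1 and 1676 without BY4741 replicate 2. Gluconeogenesis and glyoxylate cycle genes had 0 of 18 members rise and 18 fall (0 and 18 adjusted over the list alone). Gluconeogenesis members had a median of log2 -2.94, or -2.82 relative to all tested genes (camera adjusted p = 9.24e-10, and adjusted p = 0.0781 with an estimated correlation). For peroxisome and fatty acid oxidation genes 0 of 16 members rose and 15 fell (0 and 15 adjusted over the list alone), among them POX1 at log2 -4.11 ± 0.29 (adjusted p = 6.63e-06). The peroxisome median was log2 -2.75, or -2.64 relative to all tested genes (camera adjusted p = 9.04e-08, and adjusted p = 0.774 with an estimated correlation). Of 20 glycolysis and fermentation genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone), among them PFK2 by log2 1.76 ± 0.25 and PDC5 by 2.22 ± 0.32 (largest adjusted p = 0.000327). Camera gave the glycolysis list adjusted p = 0.00136, and adjusted p = 0.786 with an estimated correlation, at a median of log2 0.59, or 0.70 relative to all tested genes, with 0.75 in replicate 1 and 0.43 in replicate 2, and 0.33 with quantile normalization. Among 127 cytosolic ribosomal proteins, 99 rose and 1 fell (108 and 1 adjusted over the list alone), among them RPL13A by log2 2.33 ± 0.33 (adjusted p = 0.000293). Cytosolic ribosomal protein members had a median of log2 1.12, or 1.23 relative to all tested genes (camera adjusted p = 1.86e-15, and adjusted p = 0.774 with an estimated correlation), with 1.33 in replicate 1 and 0.87 in replicate 2.

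Mitochondrial ribosomal proteins, amino acid and ergosterol genes were higher on the arrays labelled A880STM1K than on BY4741. Mitochondrial ribosomal proteins had 48 of 66 members rise and 0 fall (51 and 0 adjusted over the list alone), among them MRPL32 by log2 3.09 ± 0.22 and MRPL7 by 2.69 ± 0.25 (largest adjusted p = 3.37e-05). The mitochondrial ribosomal protein median was log2 1.16, or 1.28 relative to all tested genes (camera adjusted p = 3.00e-14, and adjusted p = 0.774 with an estimated correlation), with 0.95 in replicate 1 and 1.47 in replicate 2. For translation factors 18 of 29 members rose and 1 fell (18 and 1 adjusted over the list alone), among them GCD11 by log2 1.75 ± 0.21 and PRT1 by 1.81 ± 0.26 (largest adjusted p = 0.000347). Camera gave the translation factor list adjusted p = 3.76e-05, and adjusted p = 0.774 with an estimated correlation, at a median of log2 0.78, or 0.90 relative to all tested genes, with 0.99 in replicate 1 and 0.64 in replicate 2. Of 38 amino acid biosynthesis genes, 27 rose and 0 fell (28 and 0 adjusted over the list alone), among them ILV3 by log2 2.66 ± 0.24 and BAT1 by 3.77 ± 0.36 (largest adjusted p = 3.65e-05). Amino acid members had a median of log2 1.42, or 1.53 relative to all tested genes (camera adjusted p = 1.98e-09, and adjusted p = 0.774 with an estimated correlation). Among 23 ergosterol synthesis genes, 21 rose and 0 fell (21 and 0 adjusted over the list alone), among them MVD1 by log2 3.64 ± 0.24 and ERG26 by 3.71 ± 0.33 (largest adjusted p = 2.24e-05). The ergosterol median was log2 1.99, or 2.10 relative to all tested genes (camera adjusted p = 2.11e-10, and adjusted p = 0.524 with an estimated correlation). Cell wall genes had 12 of 21 members rise and 3 fall (12 and 3 adjusted over the list alone), among them GAS1 by log2 3.62 ± 0.37 and CIS3 by 2.70 ± 0.41 (largest adjusted p = 0.000476). Camera gave the cell wall list adjusted p = 0.00212, and adjusted p = 0.774 with an estimated correlation, at a median of log2 1.03, or 1.14 relative to all tested genes. For auxotrophic markers 3 of 4 members rose and 0 fell (3 and 0 adjusted over the list alone), among them MET17 by log2 2.21 ± 0.45 (adjusted p = 0.00251). Marker members had a median of log2 3.09, or 3.20 relative to all tested genes (camera adjusted p = 0.00282, and adjusted p = 0.524 with an estimated correlation). URA3 is again at a bound above the median. The other 2 lists that passed camera lost the call under another scaling or without 1 array, at the adjusted p given. It was lost with quantile normalization for a-cell-specific genes (0.0517). It was lost with equal array medians for a-cell-specific genes (0.0523). It was lost without A880STM1K replicate 2 for sulfur amino acids (0.420).

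Genes that differed by at least 2-fold between A880 and BY4741 were followed on the arrays labelled A880STM1 and A880STM1K. By their average slope, these genes lay part of the way from A880 to BY4741. POP2 was detected on those arrays. The A880 strain enters both differences, so traits of A880 alone would also give a positive slope. The share therefore cannot tell an effect of the added STM1 from such traits. Chosen in 1 replicate number and measured in the other, the slope was 57.6% ± 3.69 (SD, n = 2) of a full return to BY4741 in A880STM1 and 52.0% ± 6.11 (SD, n = 2) in A880STM1K. The 838 genes chosen in replicate 1 gave 60.2% and 56.4%, and the 765 chosen in replicate 2 gave 55.0% and 47.7%. The shares of the strains differed by less than the larger SD, and no test was run on them. Single genes did not follow the average: REE1, undetected on A880, passed the BY4741 level, at 247% and 202% of a return in signal, and CAN1 lay further from BY4741 on the A880STM1 arrays, at 2193 ± 92.8 against 848 ± 103 on A880.

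Differences of the arrays labelled A880STM1 and A880STM1K, each from the A880 arrays, were compared over 5448 genes, with POP2 detected on both. Across genes, which are not independent replicates, Pearson's r was 0.574, against 0.499 on average in 100 simulations of unchanged groups that share the A880 arrays and no deviation by replicate number. The covariance was 0.577 against a simulated 0.0511, a difference of 0.526. 229 genes rose in both, where independent lists of 367 and 1025 would share 69.0, and 413 fell in both, where lists of 717 and 1533 would share 202. The 2 A880 arrays were not split between the 2 differences. The simulated covariance includes the array noise of the shared controls, with the same spread in all groups. It does not include traits of the A880 strain itself, such as its undetected genes, which enter both differences. The excess covariance therefore cannot be assigned to the added STM1. The counts for independent lists include neither, so part of the excess of shared calls may come from these controls. LEU2, HXK2 and CYC1 were among the genes that rose in both and STE18, FUS3 and AGA2 among those that fell in both, while 48 genes, SPL2 among them, were called in opposite directions.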

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

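Tests of explanations in this part were chosen after their results were seen, while the comparison of the transformed strains with each other was planned. Arrays labelled A880STM1K differed from arrays labelled A880STM1, by the direct test, for 1925 probe sets, and POP2 goes against both labels. That fit shares 1 spread over all 4 groups. The count was 1179 with only the 4 arrays compared and 794 with array weights per group, a setting chosen after seeing the data. 48 genes were called in opposite directions against A880 and passed the test of the difference. The difference was log2, with the changes of A880STM1 and of A880STM1K from A880 in brackets, -4.66 for SPL2 (1.94 and -2.72), which acts in phosphate uptake, -3.95 for BLI1 (1.72 and -2.23), -3.69 for DIF1 (2.19 and -1.498) and -3.46 for CIS1 (1.33 and -2.13). The rise on the A880STM1 arrays lost its call without A880 replicate 2 for BLI1 (adjusted p = 0.0543), and for CIS1 without A880 replicate 1 (0.0873), A880 replicate 2 (0.128) or A880STM1 replicate 1 (0.119, at log2 0.88), and their other calls against A880 and between the transformed strains held with any 1 array left out and under both scalings. Outside the main measurement, the control probe set for the 3-prime end of 25S ribosomal RNA was 24.3 times higher on the lower A880STM1 array than on the higher BY4741 array. Its signals were 22.9 on BY4741 replicate 1, 217 on BY4741 replicate 2, 72.1 on A880 replicate 1, 5600.1 on A880 replicate 2, 8301 on A880STM1 replicate 1, 5269 on A880STM1 replicate 2, 27.1 on A880STM1K replicate 1 and 6586 on A880STM1K replicate 2.

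11 of 12 genes undetected on the arrays labelled A880 and over 5 times background on BY4741 arrays, POP2 among them, were detected on all 4 arrays labelled A880STM1 or A880STM1K. For these genes as a set, the lowest median signal over background on these arrays, 10.1, argues against background or scaling. It does not exclude background for each gene. ADH7 and HXT9 were over 5 times background on both arrays of BY4741 only. ADH7, for example, had 15.4 and 20.9 on the A880STM1 arrays. An insert carrying POP2 and its neighbours would not bring back the 10 genes that lie on other chromosomes. For POP2 itself this test cannot decide, since neighbours expressed on the A880 arrays could not enter the set. RNA of BY4741 cells mixed in would bring all their abundant transcripts at the share it has for the 11 genes detected again, a median of 25.01% to 39.3% by array. At their highest on the 4 arrays, YBR013C reached 0.364%, STE18 3.07%, FUS3 7.31% and ICS2 11.5% of their BY4741 signal, which argues against it. 3 forms of that test were run, all after the values were seen. The first, the share of REE1 (247% and 202%, over a full share), also spoke against mixing but rested on 1 gene. The second found 4 of 4946 abundant genes below 15.0% and left mixing open, by a limit of more than 5 that had no deeper basis. The third asks that the third lowest gene, FUS3, lie more than 2 SD between arrays below the lowest of those medians, at 13.3%. No biological explanation was tested for this pattern, and its source stays open.

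Haploid-specific genes, a list chosen after seeing the data, were lower on the arrays labelled A880STM1 and A880STM1K than on those labelled A880. Scaling is excluded, since after quantile normalization the medians were log2 -2.15 and -2.04. Cells with both mating types active may be the source on the A880STM1 arrays. Such cells express IME4, which was higher by log2 4.23, and repress a-cell-specific genes, at a median of -2.24 against A880. Set against BY4741, STE6 was an exception, at 156 ± 43.6 on A880STM1 and 161 ± 9.32 on BY4741. The other a-cell-specific genes were lower than on BY4741. Such cells also keep alpha-cell-specific genes off, for which limma called 0 of 4 higher (0 higher and 2 lower at unadjusted p under 0.05, median -0.27, camera adjusted p = 0.917). On the A880STM1K arrays the values go both ways and leave this open: IME4 was higher by log2 3.34 and a-cell-specific genes had a median of -1.51, but 3 of 4 alpha-cell-specific genes rose (median 1.51, camera adjusted p = 0.0594), MF(ALPHA)1 from 39.8 ± 17.0 to 128 ± 39.5. The call of MF(ALPHA)1, A880STM1K against A880, was lost with quantile normalization (adjusted p = 0.0718), without A880 replicate 1 (0.143) and without A880STM1K replicate 2 (0.101). HMRA1, an a regulator that such cells need, had 1659.6 ± 1.63 on A880, 1641 ± 89.3 on A880STM1 and 616 ± 196 on A880STM1K. IME1, the inducer of meiosis, had 2224 ± 183, 1410.2 ± 164 and 167 ± 48.9 in that order, and on A880STM1K arrays it fell by log2 3.76. The added STM1 itself stays open, since STM1 was raised and these genes were lower on all 4 arrays of the transformed strains, so the design cannot separate them.

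Gluconeogenesis and glyoxylate genes were lower on the arrays labelled A880STM1K than on those labelled A880STM1. Neither scaling nor RNA quality gives this: the median was log2 -2.41 after quantile normalization, and the 5-prime probe sets of 7 control genes had a median change of -0.15, from -1.57 to 0.26, against list quartiles of -3.15, -2.59 and -1.75. A difference between the strains other than the substitution could account for it and stays open, since 2 genes, ASP3-1 and YLR156W, were detected on the A880STM1 arrays and on neither A880STM1K array. The R237K substitution, which the design names, is also open and could not be tested apart from such differences.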

How the results depend on the processing

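Among these settings, array weights per group and the return share without undetected genes were chosen after seeing the data. Across 719 calls and non-calls of named genes, none turned direction under any setting in which it was tested. The pseudocount, the floor, the other filters and no filter changed at most 1 call each. The stricter filter and the filter on the mean left some of these results untested, with 715 unchanged and 1 lost. Calls lost were 204 at adjusted p under 0.01, 81 with array weights per group, 70 with a 2-fold minimum, 66 with equal array medians, 44 without the intensity trend, 43 with only the 4 arrays compared, 32 with all probe sets and 21 with quantile normalization. Counted once for each gene result and each array left out of its comparison, 717 lost the call, 2158 kept their side and 1 gained it. STM1, A880 against BY4741, was called only with quantile normalization (adjusted p = 0.0467), the 4 arrays compared (0.0291) and array weights (0.0153).

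Counts of changed probe sets moved most with these settings. At adjusted p under 0.01 they were 220.0 for A880 against BY4741, 203 for A880STM1 against A880, 1661 for A880STM1K against A880, 1043 for A880STM1K against A880STM1 and 126 for A880STM1 against BY4741, by the construction of the threshold. Quantile normalization gave 1383 for A880 against BY4741. With only the 4 arrays compared they were 2992 for A880 against BY4741 and 1179 for A880STM1K against A880STM1, and with array weights per group 3140.0 for A880 against BY4741, 794 for A880STM1K against A880STM1 and 362 for A880STM1 against BY4741. Leaving out 1 array gave 95 to 164 for A880 against BY4741, 124 to 2283 for A880STM1 against A880, 1532 to 2634 for A880STM1K against A880, 97 to 1951 for A880STM1 against BY4741 and 1676 to 2701 for A880STM1K against BY4741; a group then rests on 1 array that is assumed to vary like the others. The main fit shares 1 spread over the groups. The median absolute log2 difference between replicates was 0.144 in BY4741, 0.118 in A880, 0.465 in A880STM1 and 0.388 in A880STM1K. With only the 4 arrays or with array weights, counts rose between the groups of smaller spread and fell between those of larger spread. Where no construction is named, causes of these moves were not tested.

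List calls were lost most with an estimated correlation, which left 0 for A880 against BY4741, 0 for A880STM1 against A880, 0 for A880STM1K against A880, 1 for A880STM1K against A880STM1, 0 for A880STM1 against BY4741 and 0 for A880STM1K against BY4741. At unadjusted p under 0.05 the estimated correlation gave 1, 2, 2, 1, 3 and 2 in the same order. Fry called 4, 5, 16, 10, 5 and 12, and quantile normalization 9 for A880STM1 against A880. Leaving out 1 array gave 10.0 to 18 lists for A880STM1K against A880STM1. 3 list results turned direction: the general stress response in A880STM1 against A880 with quantile normalization (adjusted p = 0.998), and, with 1 array left out, cytosolic ribosomal proteins, A880STM1K against A880STM1 (adjusted p from 9.33e-15 to 0.528), and ribosome biogenesis, A880STM1K against A880STM1 (from 2.21e-12 to 0.725). The turns came without A880STM1 replicate 2 (0.528) and without A880STM1K replicate 1 (0.110). The cause was not tested.

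Return shares stayed within 1 SD under each setting run, from 56.4% to 58.8% for A880STM1 and from 46.4% to 54.9% for A880STM1K. In the main fit, replicates with the same number were treated as sharing only a number, since the labels do not tie it to a batch. The control probe sets go against this. The added control RNA dap was 2.69, 2.84, 6.06 and 3.16 times higher in replicate 1 in BY4741, A880, A880STM1 and A880STM1K. The 18S ribosomal RNA 5-prime probe set was lower in replicate 1 in all groups, with ratios of 0.0938, 0.152, 0.231 and 0.0636. Of the 6 correlations between the deviations of groups, 5 ran from 0.11 to 0.29, and that of A880 with A880STM1 was 0.037. The number may therefore mark a shared deviation, and the main counts leave it out. With the replicate number as a block every count was higher: 993 for A880 against BY4741, 1374 for A880STM1 against A880, 2787 for A880STM1K against A880, 2108 for A880STM1K against A880STM1, 967 for A880STM1 against BY4741 and 2843 for A880STM1K against BY4741. The block changed no call of a named gene. Signal over background limits little here, since the filter on dim probe sets removed 2 of 5498 probe sets with 1 gene. The replicate spread, a median absolute log2 difference, was 0.144 in BY4741, 0.118 in A880, 0.465 in A880STM1 and 0.388 in A880STM1K. How far it limits the calls was not tested.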

Other observations

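The 4 gene lists in this part were chosen after seeing the data, and their tests were adjusted apart from the lists fixed earlier. Unless a value says otherwise, calls of lists and genes given here held with any 1 array left out and under both other scalings. Drug efflux genes under PDR1 and PDR3 were higher on the arrays labelled A880STM1K: 7 of 12 rose and 3 fell in A880STM1K against A880 (median log2 1.35, camera adjusted p = 0.00779, adjusted p = 0.328 with an estimated correlation) and 7 of 12 rose and 1 fell in A880STM1K against A880STM1 (median log2 1.35, camera adjusted p = 0.0121, adjusted p = 0.307 with an estimated correlation, with 1.82 in replicate 1 and 0.88 in replicate 2). In the latter, changes in log2 were PDR5 at 3.23 ± 0.25, RSB1 at 4.28 ± 0.33, PDR15 at 2.40 ± 0.27, TPO1 at 2.18 ± 0.34 and PDR10 at -2.04 ± 0.23. Genes repressed by good nitrogen sources went down between the transformed strains: 0 of 20 rose and 12 fell in A880STM1K against A880STM1 (median log2 -1.36, camera adjusted p = 5.04e-05, adjusted p = 0.100 with an estimated correlation, with -1.04 in replicate 1 and -1.71 in replicate 2), with GAP1 at -3.80 ± 0.29, MEP1 at -3.09 ± 0.26, PUT4 at -3.48 ± 0.31 and MEP2 at -3.55 ± 0.33. On the A880STM1 arrays, 6 of 20 rose and 1 fell in A880STM1 against A880 (median log2 0.47, camera adjusted p = 7.56e-05, adjusted p = 0.0628 with an estimated correlation, with 0.15 with quantile normalization, and 0.86 with equal array medians), with DAL5 and MEP2 raised by 2.65 ± 0.26 and 3.04 ± 0.33. In the pentose phosphate pathway, which makes NADPH, 5 of 10 rose and 2 fell in A880STM1K against A880 (median log2 0.46, camera adjusted p = 0.0522, adjusted p = 0.207 with an estimated correlation, with 0.81 with equal array medians); GND1 at 2.89 ± 0.24, SOL3 at 2.96 ± 0.28 and TKL1 at 3.27 ± 0.43 rose, and their paralogs or partners GND2 at -2.03 ± 0.52 and TKL2 at -1.70 ± 0.26 fell, the first losing its call without A880STM1K replicate 1 (log2 -1.09, adjusted p = 0.0639).

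Haploid-specific genes, whose products serve mating or are shut off in diploids, fell on the arrays of both transformed labels: 0 of 12 rose and 11 fell in A880STM1 against A880 (median log2 -2.44, camera adjusted p = 3.58e-11, adjusted p = 0.0628 with an estimated correlation) and 0 of 12 rose and 10 fell in A880STM1K against A880 (median log2 -2.14, camera adjusted p = 4.01e-05, adjusted p = 0.207 with an estimated correlation). NEJ1, a repair factor of this kind, had 244 ± 44.0 on A880, 35.5 ± 19.0 on A880STM1 and 55.3 ± 37.5 on A880STM1K, and its call in A880STM1 against A880 was lost without A880 replicate 2 (log2 -2.70, adjusted p = 0.0501). IME4 had 39.9 ± 2.41 on BY4741, 23.2 ± 4.29 on A880, 455 ± 199 on A880STM1 and 235 ± 51.8 on A880STM1K. Signals of HMLALPHA1, an alpha regulator, were 22.1 ± 6.24, 26.5 ± 5.61, 41.7 ± 13.1 and 90.9 ± 43.0 in the same order, and those of HMRA1, an a regulator, 2905 ± 214, 1659.6 ± 1.63, 1641 ± 89.3 and 616 ± 196.

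Of the genes deleted in the usual BY4741, 2 gave signal on the BY4741 arrays, 1447 ± 1037 for MET17 and 536 ± 8.43 for LEU2, while URA3 lay at 2.23 ± 1.54. HIS3, a marker not counted among these, had 629 ± 53.6. CAN1 had 0.435 ± 0.165 on BY4741, 848 ± 103 on A880, 2193 ± 92.8 on A880STM1 and 629.7 ± 64.3 on A880STM1K. Replicates also differed in control probe sets by number: dap, a control RNA added to samples, was higher in replicate 1 than in replicate 2 by 2.69, 2.84, 6.06 and 3.16 times in BY4741, A880, A880STM1 and A880STM1K. The 18S ribosomal RNA 5-prime probe set had ratios of 0.0938, 0.152, 0.231 and 0.0636 in that order. The geometric mean ratio of 3-prime to 5-prime signal over 7 control genes was 1.84 and 1.83 on the A880STM1K arrays and 1.503 to 1.70 on the others.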
